A study of Homo sapiens with 24 samples.

How the data were processed

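RNA from 24 samples of the human breast cancer cell line MCF-7 was sequenced, 3 samples in each of 8 groups. The groups crossed 4 lines with 24 h in either 10 µM C8-ceramide or its ethanol vehicle. The lines were the parental, endocrine-sensitive MCF-7 and 3 endocrine-resistant derivatives, called MCF-7-FULR, MCF-7-HER2 and MCF-7-TAMR in the labels and FULR, HER2 and TAMR here. Per the labels' protocols, parental cells grew in RPMI with phenol red and 10% FBS, while the other 3 lines grew in phenol red-free medium with 10% charcoal-stripped FBS, which holds little estrogen. The FULR medium also held fulvestrant at 1e-07 M, an estrogen receptor degrader, and the TAMR medium 4-hydroxytamoxifen at 1e-07 M, a receptor antagonist. Line, medium and drug therefore changed together in every comparison of a resistant line with the parental line, while each ceramide comparison was within 1 line and 1 medium. No label says whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

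Libraries were made from 7 to 80 ng of total RNA after ribosomal RNA depletion with the CORALL kit, which adds unique molecular identifiers, with 15 PCR cycles, and were read as pairs of 150 nt, per the labels' protocols. The molecule label instead reads polyA RNA, which was not settled here. Levels of RNAs without a poly(A) tail, such as replication-dependent histone mRNAs (0.145% to 0.5% of counts per library), depend on it. The deposited values were whole-number counts per gene in 1 table, which the authors made with STAR and featureCounts on hg38, per the submitters' processing notes; no versions are given there. Whether counting used strand or collapsed identifiers is not given in the sources used here, so antisense and overlapping genes cannot be parted, and counts may include PCR copies. Counts of genes with near-identical copies (ribosomal proteins, histones, HSPA1A and HSPA1B, the AKR1C genes, processed pseudogenes) are uncertain, since reads can fall on either copy. The table held 43836 gene rows, of which 43564 identifiers matched GENCODE 29 on GRCh38, the source of the names and coordinates used here. The 37 rows for the second copy of genes shared by both sex chromosomes held 28 counts in all. Every column of the table was mapped to 1 sample by its name. Library totals ran from 12727770 to 26312258 counts. A floor of 3 counts over the 3 libraries of a group corresponded to 0.0442 to 0.0737 CPM (counts scaled to library size), and such floors and intervals cover counting error only.

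Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (17769 genes kept), 1 model over all 8 groups, and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Standard errors of log2 fold changes were approximated as the fold change divided by the square root of F. The comparisons were ceramide against vehicle in each line, the difference of each resistant line's response from the parental response (an interaction), any difference in response among the 4 lines (an F test), and each resistant line against parental in vehicle. HER2 was compared with TAMR, and the responses of the resistant lines with each other, only after the data had been seen. All groups shared 1 estimate of the spread, while the common biological coefficient of variation by line was 0.117 in parental, 0.174 in FULR, 0.076 in HER2 and 0.165 in TAMR. On counts simulated from these samples with 100 genes changed 2-fold and 100 changed 4-fold among 17033 genes, the parental ceramide test recovered 62% and 79% of them, with 10 false calls. In FULR it recovered 61% and 87% among 17045 genes, with 81 false calls. In HER2 it recovered 67% and 82% among 17079 genes with 0 false calls, and in TAMR 62% and 88% among 17039 genes with 75. In FULR and TAMR the false calls thus far exceeded the share of 0.05 that the threshold allows. Tests of a difference in response from parental gave 26, 3 and 16 false calls in FULR, HER2 and TAMR, and recovered 42%, 50% and 45% of the 2-fold changes. Comparisons with parental in vehicle gave 28, 3 and 21. The F test among the 4 lines gave 27, 22 and 14 with FULR, HER2 or TAMR changed. DESeq2 gave 21 in the parental ceramide test and 150 in that of FULR. Counts of calls by these tests, above all in FULR and TAMR, may therefore hold more false ones than the threshold states.

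Lists of genes were fixed, like the groups, the tests and most of the other settings tried, before the data were examined. They covered PERK-ATF4 targets of the integrated stress response (ISR), ISR amino acid metabolism, aminoacyl-tRNA synthetases, ER chaperones, XBP1 targets with ER-associated degradation, ER stress sensors, apoptosis regulators, sphingolipid metabolism, cholesterol synthesis, fatty acid synthesis, LXR cholesterol efflux, estrogen response, luminal identity, basal and mesenchymal genes, the HER family with 17q12 neighbours, proliferation, p53 targets, NRF2 oxidative stress, heat shock, autophagy and lysosome, interferon response, NF-kB inflammatory genes, hypoxia, immediate early genes, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, drug efflux and metabolism, leukocyte markers, and fibroblast and endothelial markers. Of their members 1, H3C2, was not found in the table. Each list except the leukocyte markers was tested with camera (limma 3.58.1), which compares a list with all other genes at a preset correlation of 0.01. It was tested again with the correlation estimated from the data, each adjusted over the lists tested. The fry test asked whether a list moved one way.

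Genes are named by a rule: the 6 largest rises and falls per comparison among called genes with a mean of at least 5 CPM and no overlap between groups, up to 4 called members of each list or the 2 with the smallest p, and 14 genes followed in every comparison. Sex-linked marker genes were passed over. A fold against a group with 0 counts is given as a lower bound from the floor, and 1 with 1 to 3 counts with its 95% counting interval. Alternatives were RLE scaling, no filter and a stricter one, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and for lists fry and the estimated correlation; added after the data had been seen, both libraries that stood apart were left out together. Alternatives that change a result are named with it, except fry, which is mostly given only as counts of lists. Fry called some lists that camera did not. In HER2 with ceramide these included interferon genes (fry adjusted p = 0.000377) but not hypoxia genes (0.3). A list without a camera call is therefore not shown to be unchanged.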

Results

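Gene expression was measured by RNA sequencing in 24 MCF-7 samples, 3 in each of 8 groups. The study asked how C8-ceramide, a short-chain, cell-permeable form of the sphingolipid ceramide, acts on breast cancer cells that respond to endocrine therapy (parental) and on 3 lines that resist it (FULR, HER2 and TAMR). Library totals ran from 12727770 to 26312258 counts, and 14193 to 16109 genes had at least 10 counts in a library. Replicates correlated at a Spearman coefficient of 0.978 to 0.995 across genes. All replicate pairs differed by more than sampling noise, with a chi-square of 5.74 to 49.95 per degree of freedom, so no library was counted as a copy of another. Values after ± are standard errors of log2 fold changes unless SD is stated, and every group had n = 3.

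The first principal component, with 50.4% of the variance, set parental and FULR libraries apart from HER2 and TAMR libraries. The second held 18.7% and set FULR apart from parental. It also parted ceramide from vehicle libraries in FULR, HER2 and TAMR. The third held 11.7% and parted ceramide from vehicle libraries in these lines too, most widely in HER2 and TAMR. The 6 parental libraries lay together whatever their treatment. A pair of libraries stood apart from their sisters. The ceramide response of FULR ceramide library 3 spread over genes with an SD of 0.89 on the log2 scale, against 0.60 and 0.66 in its sisters, and that of TAMR ceramide library 1 with an SD of 0.87, against 1.07 and 1.13. The share of counts from MALAT1, a nuclear RNA named after its values were seen, went with ceramide from 1.48% ± 0.0413 to 2.11% ± 0.218 in FULR, 2.33% ± 0.0858 to 3.35% ± 0.302 in HER2 and 1.34% ± 0.018 to 2.85% ± 0.149 in TAMR, against 2% ± 0.0527 to 2.16% ± 0.254 in parental (SD).

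**Figure D1:**
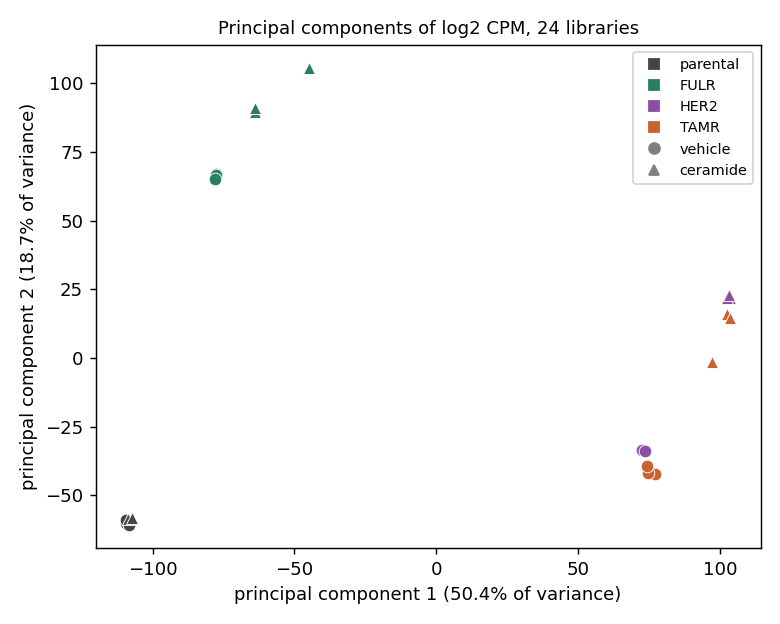
Principal components 1 and 2 of log2 CPM over the 24 libraries, 1 point per library, with its axis labels giving the percent of variance (50.4% and 18.7%). Parental ceramide points lie beside parental vehicle points, while in FULR, HER2 and TAMR the ceramide points lie away from the vehicle points.

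Ceramide changed few genes in parental cells by this test. The stress transcription factor genes DDIT3 (0.31 ± 0.20, adjusted p = 0.574), ATF3 (0.21 ± 0.59, adjusted p = 0.947) and ATF4 (0.28 ± 0.09, adjusted p = 0.196) were not called. Neither was the ER chaperone gene HSPA5 (0.38 ± 0.16, adjusted p = 0.332). The estrogen receptor gene ESR1 (0.08 ± 0.15), its target PGR, the progesterone receptor (0.21 ± 0.17), and ERBB2, which encodes HER2 (-0.09 ± 0.12), were not called either. The single call was RPS3P7 (ENSG00000243101.1, chromosome 16, 78825281 to 78826006, hg38), a processed pseudogene of a ribosomal protein that shares reads with its parent gene. It was at 2.44 ± 0.28 CPM in vehicle and 0.516 ± 0.0991 CPM in ceramide (SD). It was chosen for naming after its values were seen, and its log2 fold change was -2.22 (adjusted p = 0.0333). The call ended with the replicate number as a block (adjusted p = 0.0691) and without any 1 of parental vehicle library 1 (0.0758), 2 (0.179) or 3 (0.169) or parental ceramide library 2 (0.0513) or 3 (0.519). No gene was called, either, without FULR ceramide library 1, TAMR vehicle library 2 or TAMR vehicle library 3.

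Over all 17769 genes tested in parental cells, 0 rose and 1 fell, while 2116 had an unadjusted p below 0.05 and DESeq2 called 272. The count changed with the settings. It was 17 when only the parental libraries were fitted, 133 with no filter on low counts and 0 with the replicate number as a block. Leaving out single libraries gave 0 (without parental vehicle library 1) to 80 (without FULR ceramide library 3, which is in neither parental group). Leaving out both libraries that stood apart gave 524, of which 257 were among the DESeq2 calls. Those 524 had a median absolute log2 fold change of 0.396. Among them were 22 of 27 ribosomal protein genes and 9 of 25 nuclear oxidative phosphorylation genes, all higher in ceramide.

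Ribosomal protein genes had a median log2 fold change of 0.328 in parental cells, with 0 of 27 called over all genes and 25 higher when adjusted over the list alone (camera adjusted p = 4.2e-24; adjusted p = 0.322 with an estimated correlation). RPS19 (0.41 ± 0.10) and RPL5 (0.39 ± 0.10) had the smallest p-values, at adjusted p = 0.105 and 0.121. DESeq2 called both, at 0.0107 and 0.0175. Nuclear oxidative phosphorylation genes had a median of 0.309, with 0 of 25 called and 14 higher when adjusted over the list alone (camera adjusted p = 1.15e-12; adjusted p = 0.322 with an estimated correlation). The complex III genes UQCRQ (0.47 ± 0.13) and UQCRC1 (0.35 ± 0.10) led them, and were called by DESeq2 at 0.0405 and 0.0277. ER chaperones had a median of 0.266, with 0 of 19 called and 5 higher when adjusted over the list alone (camera adjusted p = 2.8e-08; adjusted p = 0.322 with an estimated correlation). PPIB (0.38 ± 0.09) and PDIA6 (0.38 ± 0.10), which fold secreted proteins, led, and DESeq2 called them at 0.00384 and 0.0184. PERK-ATF4 targets had a median of 0.228, or 0.209 with genes at the floor set to their bounds, with 2 of 20 higher when adjusted over the list alone (camera adjusted p = 0.00679; adjusted p = 0.573 with an estimated correlation). Of 12 lists called by camera in parental cells, 0 held with an estimated correlation and 3 with fry.

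**Figure D2:**
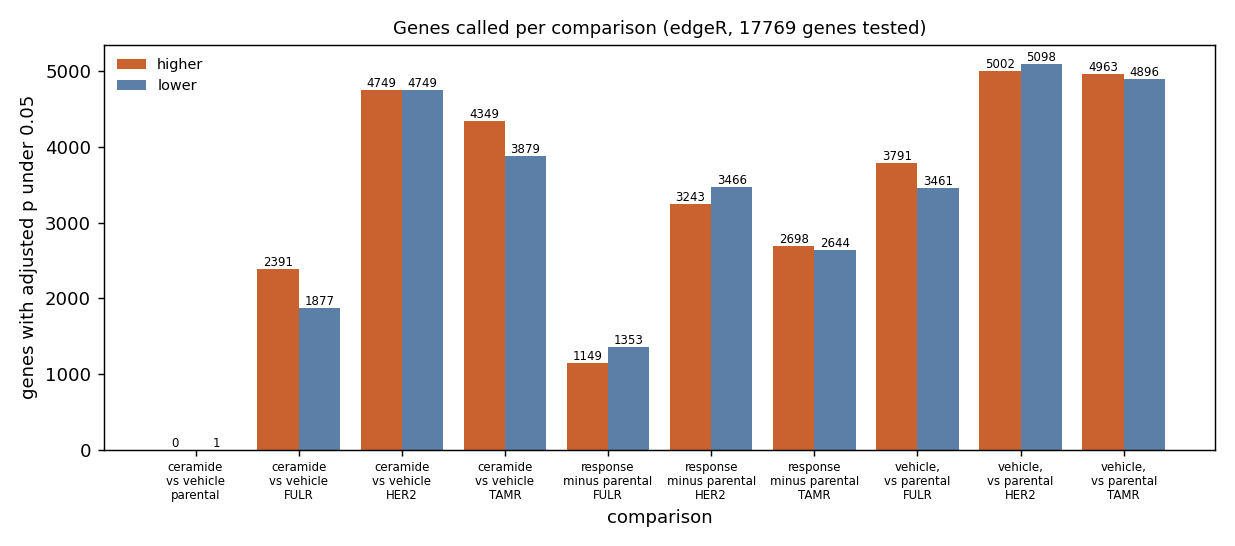
Number of genes called higher (orange bars) and lower (blue bars) in each comparison, out of 17769 tested: ceramide against vehicle in each line, each resistant line's response minus the parental one, and each resistant line against parental in vehicle. Ceramide against vehicle gave 0 and 1 in parental, 2391 and 1877 in FULR, 4749 and 4749 in HER2, and 4349 and 3879 in TAMR.

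In FULR cells, ceramide raised PERK-ATF4 targets and amino acid metabolism genes and lowered proliferation genes. DDIT3 (ENSG00000175197.11, chromosome 12, 57516588 to 57521737), which encodes the stress factor CHOP, rose by 2.15 ± 0.17 on the log2 scale (adjusted p = 1.16e-09). NIBAN1, a stress-induced gene that affects translation, rose by 5.56 ± 0.33, and IL6, an inflammatory cytokine, by 5.998 ± 1.02. INHBE, a hepatokine gene of the activin family, rose by 4.71 ± 0.53. The replication genes FAM111B (-2.59 ± 0.20), ASF1B, a histone chaperone (-2.15 ± 0.19), DTL (-2.13 ± 0.19) and PCLAF, a PCNA-binding factor (-2.12 ± 0.21), fell most. In all, 2391 genes rose and 1877 fell, 730 and 551 of them at least 2-fold. The 4268 calls became 2444 (1094 rises, 1350 falls) when only the FULR libraries were fitted, 2781 (1252 and 1529) without FULR ceramide library 3, 3094 (1531 and 1563) without FULR vehicle library 2 and 3470 (1575 and 1895) without both libraries that stood apart, so the excess of rises did not hold. Without that library the changes of IL6, NIBAN1 and INHBE were 3.74, 4.79 and 4.08, that of IL6 was 8.45 without FULR vehicle library 2, and that of INHBE was 4.13 or 5.50 without FULR vehicle library 1 or 2.

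Among PERK-ATF4 targets in FULR cells, 18 of 20 rose and 0 fell (camera adjusted p = 1.21e-37; adjusted p = 0.00154 with an estimated correlation). They included SLC7A11, the cystine importer (3.42 ± 0.28), ATF3 (3.18 ± 0.40), CHAC1, which degrades glutathione (3.02 ± 0.29), and ATF4 itself (0.82 ± 0.09, adjusted p = 1.52e-07). Without FULR ceramide library 3, SLC7A11 was at 2.74 and ATF3 at 2.18. Amino acid metabolism genes rose in 13 of 15 cases (camera adjusted p = 3.51e-13; adjusted p = 0.00514 with an estimated correlation), with the serine and one-carbon enzyme genes SHMT2 (1.52 ± 0.14) and MTHFD2 (1.20 ± 0.10) among them. Of 18 aminoacyl-tRNA synthetases 12 rose (camera adjusted p = 1.26e-14; adjusted p = 0.0568 with an estimated correlation), led by WARS1 (1.99 ± 0.14). ER chaperones rose in 18 of 19 cases (camera adjusted p = 3.26e-11; adjusted p = 0.0736 with an estimated correlation), led by HYOU1 (1.68 ± 0.19). HSPA5 (ENSG00000044574.7, chromosome 9, 125234853 to 125241330) rose by 1.22 ± 0.16. Of XBP1 targets and degradation genes 21 of 22 rose (camera adjusted p = 1.31e-19; adjusted p = 0.0736 with an estimated correlation), among them the co-chaperone gene DNAJB9 (2.26 ± 0.27; 1.53 without FULR ceramide library 3), HERPUD1 (1.26 ± 0.17) and XBP1 (0.60 ± 0.13). ER stress sensors rose in 5 and fell in 1 of 12 cases (camera adjusted p = 0.0103; adjusted p = 0.0999 with an estimated correlation), with ERN1, which encodes IRE1, at 1.92 ± 0.23 and ATF6 at 1.27 ± 0.18.

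Lipid synthesis genes rose in FULR cells. Of 25 cholesterol synthesis genes 22 rose (camera adjusted p = 4.57e-24, or adjusted p = 0.0566 with an estimated correlation). They were led by HMGCS1, an HMG-CoA synthase gene (2.20 ± 0.22, or 1.54 without FULR ceramide library 3), and MSMO1 (1.82 ± 0.19). Of 15 fatty acid synthesis genes 11 rose (camera adjusted p = 3.18e-07; adjusted p = 0.0999 with an estimated correlation), with ACSS2, which makes acetyl-CoA, at 2.01 ± 0.21 and the desaturase gene SCD at 0.93 ± 0.19. Sphingolipid metabolism genes, which act on ceramide, rose in 4 and fell in 4 of 38 cases (camera adjusted p = 0.478). The ceramide synthase gene CERS4 (-0.67 ± 0.18) was the largest, and its call ended without FULR ceramide library 3 (-0.52, adjusted p = 0.0553) and when only FULR libraries were fitted (adjusted p = 0.11). LXR targets of cholesterol efflux rose in 1 and fell in 1 of 7 cases (camera adjusted p = 0.907).

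Of 29 proliferation genes 27 fell in FULR cells and 0 rose (camera adjusted p = 8.6e-46; adjusted p = 1.05e-05 with an estimated correlation). RRM2 (ENSG00000171848.13, chromosome 2, 10120698 to 10131419), a subunit of ribonucleotide reductase, fell by 2.04 on the log2 scale, from 245 ± 13.7 to 59.6 ± 3.87 CPM (SD), and MCM10, a replication initiation factor, by 2.03. Replication-dependent histone genes fell in 19 of 21 cases (camera adjusted p = 7.27e-20; adjusted p = 0.0736 with an estimated correlation), led by H1-5 (-1.78 ± 0.19); these mRNAs lack a poly(A) tail, and the labels disagree on how RNA was selected. Nuclear oxidative phosphorylation genes fell in 16 of 25 cases (camera adjusted p = 7.18e-07; adjusted p = 0.207 with an estimated correlation). Heat shock genes fell in 8 of 14 cases and rose in 1 (camera adjusted p = 0.00178; adjusted p = 0.249 with an estimated correlation), with the co-chaperone gene BAG3 at -0.95 ± 0.15 and HSP90AA1 at -0.73 ± 0.13. Mitochondrially encoded genes fell in 1 of 13 cases, or 9 when adjusted over the list alone (camera adjusted p = 0.00352; adjusted p = 0.422 with an estimated correlation), as the share of counts from these genes went from 6.15% ± 0.0894 to 4.58% ± 0.925 (SD) with ceramide. The 1 gene, MT-ND2 (-0.50 ± 0.16), lost its call without FULR vehicle library 1 (adjusted p = 0.0549) or 2 (0.0625) or FULR ceramide library 3 (0.115).

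Some genes of inflammation and oxidative stress also rose in FULR cells. NF-kB genes rose in 7 of 14 cases (median 0.66, or 0.86 with genes at the floor set to their bounds; camera adjusted p = 0.00734; adjusted p = 0.162 with an estimated correlation). NRF2 genes rose in 12 of 19 cases (camera adjusted p = 1.48e-07; adjusted p = 0.162 with an estimated correlation), with HMOX1, heme oxygenase 1, at 2.73 ± 0.42, and at 1.38 without FULR ceramide library 3. Autophagy and lysosome genes rose in 12 and fell in 1 of 21 cases (camera adjusted p = 0.000733; adjusted p = 0.0999 with an estimated correlation), with MAP1LC3B, the LC3B gene, at 1.65 ± 0.24, and 1.04 without that library. Immediate early genes rose in 9 and fell in 1 of 16 cases (camera adjusted p = 9.66e-05; adjusted p = 0.0999 with an estimated correlation). EGR3 had no counts in FULR vehicle and was at least 20.7-fold higher in ceramide. P53 targets rose in 6 and fell in 1 of 18 cases (camera adjusted p = 0.00244; adjusted p = 0.167 with an estimated correlation), with GDF15, a stress-induced secreted factor, at 2.73 ± 0.20. Drug efflux and metabolism genes rose in 6 of 12 cases (camera adjusted p = 0.04; adjusted p = 0.0999 with an estimated correlation), and the call ended without FULR vehicle library 1 (0.0551) or 3 (0.0676) or FULR ceramide library 2 (0.053). The xenobiotic-metabolising cytochrome gene CYP1A1 rose by 2.45 ± 0.32, or 1.65 without FULR ceramide library 3.

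The estrogen and progesterone receptor genes were low in FULR cells before treatment and were not called with ceramide. ESR1 was at 1.36 ± 0.665 CPM in vehicle (SD; log2 fold change -0.52 ± 0.36, adjusted p = 0.328), PGR had no counts in either group, GREB1, an estrogen target, was at -0.25 ± 0.16 and ERBB2 at -0.18 ± 0.12. TFF1, a secreted estrogen target, was at -0.60 ± 0.29 (adjusted p = 0.137) and was called without the filter (2.17e-05) and with only FULR libraries fitted (0.043). Estrogen response genes rose in 7 and fell in 5 of 27 cases (camera adjusted p = 0.718). Apoptosis regulators rose in 7 and fell in 4 of 23 cases (camera adjusted p = 0.333), with the BH3-only gene PMAIP1 at 2.01 ± 0.26.

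In HER2 cells, ceramide raised PERK-ATF4 targets and NF-kB inflammatory genes and lowered proliferation genes. DDIT3 rose by 4.77 ± 0.19 (adjusted p = 6.7e-16), from 17.8 ± 1.52 to 484 ± 10.6 CPM (SD). PTGS2 (ENSG00000073756.11, chromosome 1, 186671791 to 186680427), the inducible cyclooxygenase, rose by 10.73 ± 0.52, to 112 ± 30.8 CPM (SD). NEURL3, a ubiquitin ligase gene, had 1 count in vehicle and was 1030-fold higher (184 to 40700). LTB, lymphotoxin beta, with 2 counts, was 540-fold higher (149 to 4460). MOV10L1, a germline helicase gene, with 3 counts, was 422-fold higher (144 to 2050). MAB21L4 (-6.47 ± 0.57), ID1, a BMP target (-6.14 ± 0.62), the integrin gene ITGB6 (-5.64 ± 0.46) and SMAD6, an inhibitor of BMP signalling (-5.64 ± 0.45), fell most, with SMAD6 at -6.30 without HER2 ceramide library 1. Fitted log2 fold changes were 11.03 for NEURL3 without HER2 vehicle library 1, 11.14 for LTB without library 3, and 7.90 or 11.34 for MOV10L1 without library 1 or 2. In all, 4749 genes rose and 4749 fell, 1975 and 2377 of them at least 2-fold.

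PERK-ATF4 targets rose in 18 of 20 cases in HER2 cells (camera adjusted p = 2.09e-21; adjusted p = 0.0126 with an estimated correlation), among them ATF3 (5.05 ± 0.39), SLC7A11 (4.32 ± 0.29), CHAC1 (3.55 ± 0.27) and ATF4 (1.24 ± 0.09). Amino acid metabolism genes rose in 10 and fell in 1 of 15 cases (camera adjusted p = 8.66e-06; adjusted p = 0.082 with an estimated correlation), with PHGDH, the first enzyme of serine synthesis, at 1.67 ± 0.12. Aminoacyl-tRNA synthetases rose in 14 and fell in 2 of 18 cases (camera adjusted p = 1.96e-13; adjusted p = 0.0798 with an estimated correlation). ER chaperones rose in 16 and fell in 1 of 19 cases (camera adjusted p = 4.68e-06; adjusted p = 0.236 with an estimated correlation), with HSPA5 at 1.86 ± 0.16. XBP1 targets and degradation genes rose in 20 of 22 cases (camera adjusted p = 3.16e-11; adjusted p = 0.236 with an estimated correlation), with DNAJB9 at 3.71 ± 0.29 and HERPUD1 at 2.88 ± 0.18. XBP1 itself rose by 0.33 ± 0.12 (adjusted p = 0.0256), a call lost without HER2 vehicle library 2 (0.0982) or 3 (0.054) or HER2 ceramide library 2 (0.0672) or 3 (0.0797). ER stress sensors rose in 4 and fell in 3 of 12 cases (camera adjusted p = 0.194), with ERN1 at 3.36 ± 0.23.

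NF-kB genes rose in 11 and fell in 2 of 14 cases in HER2 cells (median 4.40, or 3.86 with genes at the floor set to their bounds; camera adjusted p = 2.41e-10; adjusted p = 0.0126 with an estimated correlation). The chemokine gene CCL2 was at least 125-fold higher and CCL20 at least 34.7-fold higher, both with no counts in vehicle, and TNF, with 2 counts, was 314-fold higher (86.4 to 2600). P53 targets rose in 15 and fell in 2 of 18 cases (camera adjusted p = 0.00013; adjusted p = 0.172 with an estimated correlation). Apoptosis regulators rose in 10 and fell in 7 of 23 cases (camera adjusted p = 0.283), with the pro-apoptotic genes HRK (3.87 ± 0.34), PMAIP1 (2.79 ± 0.23) and BBC3 (2.10 ± 0.20) among the rises. Autophagy and lysosome genes rose in 11 and fell in 6 of 21 cases (camera adjusted p = 0.0225; adjusted p = 0.334 with an estimated correlation), led by OPTN, an autophagy receptor (3.74 ± 0.25). NRF2 genes rose in 13 and fell in 4 of 19 cases (camera adjusted p = 0.00888; adjusted p = 0.619 with an estimated correlation). The leukocyte marker ITGAM, 1 of 2 such markers tested, had no counts in vehicle and was at least 52-fold higher, at 2.29 CPM.

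ESR1 (ENSG00000091831.22, chromosome 6, 151656691 to 152129619) fell by 2.31 on the log2 scale in HER2 cells, from 1064 ± 40.1 to 215 ± 7.48 CPM (SD), and PGR by 2.08. ERBB2 (ENSG00000141736.13, chromosome 17, 39687914 to 39730426) fell by 1.54, from 362.5 ± 17.3 to 124 ± 5.05 CPM (SD), and ERBB3, its signalling partner, by 1.60. In contrast GREB1 rose by 1.93 ± 0.15 and TFF1 by 2.63 ± 0.28. Estrogen response genes rose in 8 and fell in 12 of 27 cases (camera adjusted p = 0.594). HER family and 17q12 genes rose in 3 and fell in 5 of 13 (camera adjusted p = 0.28). Luminal identity genes rose in 4 and fell in 9 of 16 (camera adjusted p = 0.0128; adjusted p = 0.186 with an estimated correlation), with SPDEF, a luminal transcription factor, at -2.36 ± 0.24. Proliferation genes fell in 19 of 29 cases (camera adjusted p = 2.38e-09; adjusted p = 0.0235 with an estimated correlation), with E2F1 at -2.82 ± 0.29 and RRM2 at -2.76 ± 0.15. Fatty acid synthesis genes rose in 5 and fell in 7 of 15 cases (camera adjusted p = 0.21), with FASN, fatty acid synthase, at -1.51 ± 0.13. Cholesterol synthesis genes rose in 6 and fell in 4 of 25 (camera adjusted p = 0.794). Sphingolipid genes rose in 7 and fell in 10 of 38 (camera adjusted p = 0.386), with the ceramide kinase gene CERK at -1.28 ± 0.13. Nuclear oxidative phosphorylation genes fell in 13 and rose in 1 of 25 cases (camera adjusted p = 0.0188; adjusted p = 0.705 with an estimated correlation). Mitochondrially encoded genes fell in 7 of 13 (camera adjusted p = 0.09), as their share of counts went from 5.82% ± 0.28 to 4.15% ± 0.418 (SD).

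In TAMR cells, ceramide raised PERK-ATF4 targets, NF-kB inflammatory genes and heat shock genes and lowered proliferation genes. CYP1A1 (ENSG00000140465.13, chromosome 15, 74719542 to 74725610) rose by 11.43 ± 0.58, to 360 ± 109.6 CPM (SD; adjusted p = 3.24e-14). TNF, with no counts in vehicle, was at least 250-fold higher. PTGS2 rose by 9.81 ± 0.46 (11.09 without TAMR vehicle library 1), HSPA6, a stress-inducible chaperone gene, by 9.20 ± 0.34 (9.89 without that library), and BIRC3, an apoptosis inhibitor and NF-kB target, by 7.31 ± 0.39. The mucin gene MUC5B (-3.20 ± 0.37; -4.06 without TAMR ceramide library 1), SYT12, a synaptotagmin (-3.17 ± 0.33), and DNM3, a dynamin (-3.12 ± 0.34; -2.35 without TAMR vehicle library 3), fell most. In all, 4349 genes rose and 3879 fell, 1804 and 1460 of them at least 2-fold.

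PERK-ATF4 targets rose in 18 of 20 cases in TAMR cells (median 1.98, or 1.95 with genes at the floor set to their bounds; camera adjusted p = 3.73e-26; adjusted p = 0.00522 with an estimated correlation). ATF3 rose by 5.72 ± 0.40, PPP1R15A, the phosphatase subunit GADD34, by 4.96 ± 0.33, CHAC1 by 4.08 ± 0.29 and DDIT3 by 3.78 ± 0.18. Heat shock genes rose in 10 of 14 cases and fell in 0 (camera adjusted p = 2.63e-16; adjusted p = 0.0134 with an estimated correlation), with HSPA1A (4.60 ± 0.20) and HSPA1B (4.39 ± 0.17), near-identical copies that share reads, and DNAJB1 (2.83 ± 0.13). In HER2 the same list rose in 5 and fell in 4 cases (camera adjusted p = 0.145, fry adjusted p = 0.00409). NF-kB genes rose in all 14 cases in TAMR (median 5.64, or 5.34 with genes at the floor set to their bounds; camera adjusted p = 3.41e-26; adjusted p = 0.000347 with an estimated correlation), with CCL2 at least 87.3-fold and IL6 at least 42-fold higher. Autophagy and lysosome genes rose in 12 and fell in 1 of 21 cases (camera adjusted p = 5.76e-05; adjusted p = 0.0704 with an estimated correlation), led by OPTN (5.94 ± 0.30). Apoptosis regulators rose in 13 and fell in 3 of 23 (camera adjusted p = 0.00788; adjusted p = 0.177 with an estimated correlation), with BBC3 at 3.41 ± 0.22 and BCL2, which blocks apoptosis, at -1.95 ± 0.24. Immediate early genes rose in 6 and fell in 5 of 16 (camera adjusted p = 0.0665), with JUN at 4.45 ± 0.19. Drug efflux and metabolism genes rose in 6 and fell in 3 of 12 (camera adjusted p = 0.0162; adjusted p = 0.0704 with an estimated correlation), with CYP1B1 at 4.35 ± 0.29 and TIPARP, an aryl hydrocarbon receptor target, at 2.93 ± 0.25. ITGAM, with no counts in vehicle, was at least 37.8-fold higher, at 1.76 CPM.

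ER chaperones rose in 8 and fell in 2 of 19 cases in TAMR cells (camera adjusted p = 0.0654), with HSPA5 at 0.87 ± 0.16. XBP1 targets and degradation genes rose in 16 and fell in 1 of 22 (camera adjusted p = 1.25e-05; adjusted p = 0.443 with an estimated correlation), with DNAJB9 at 3.64 ± 0.29, HERPUD1 at 2.36 ± 0.17 and XBP1 at 0.98 ± 0.13. Amino acid metabolism genes rose in 10 and fell in 1 of 15 (camera adjusted p = 0.00982; adjusted p = 0.294 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 13 and fell in 2 of 18 (camera adjusted p = 0.000674; adjusted p = 0.443 with an estimated correlation). Proliferation genes fell in 21 of 29 cases (camera adjusted p = 5.45e-12; adjusted p = 0.0116 with an estimated correlation), with RRM2 at -2.27 ± 0.15 and E2F1 at -2.11 ± 0.27, or -2.73 without TAMR ceramide library 1. Estrogen response genes rose in 3 and fell in 12 of 27 (camera adjusted p = 0.0126; adjusted p = 0.0704 with an estimated correlation), with IGFBP5, which binds insulin-like growth factors, at -2.86 ± 0.56 and the cyclin D1 gene CCND1 at -1.83 ± 0.25, or -4.70 and -2.57 without TAMR ceramide library 1. ESR1 fell by 1.41 and PGR by 1.87. ERBB2 (0.15 ± 0.12, adjusted p = 0.307) was not called and was at -0.01 without TAMR ceramide library 1. TFF1 (0.35 ± 0.26, adjusted p = 0.282) was not called either, and was at -0.26 without that library and near 0 without TAMR vehicle library 3. GREB1 (-0.43 ± 0.29, adjusted p = 0.236) was called without TAMR ceramide library 2 (-1.03, adjusted p = 0.00763). Fatty acid synthesis genes rose in 2 and fell in 6 of 15 (camera adjusted p = 0.0124; adjusted p = 0.491 with an estimated correlation), with FASN at -1.81 ± 0.13. Cholesterol synthesis genes rose in 9 and fell in 3 of 25 (camera adjusted p = 0.313). Sphingolipid genes rose in 5 and fell in 8 of 38 (camera adjusted p = 0.638), with UGCG, glucosylceramide synthase, at 0.72 ± 0.13.

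**Figure D3:**
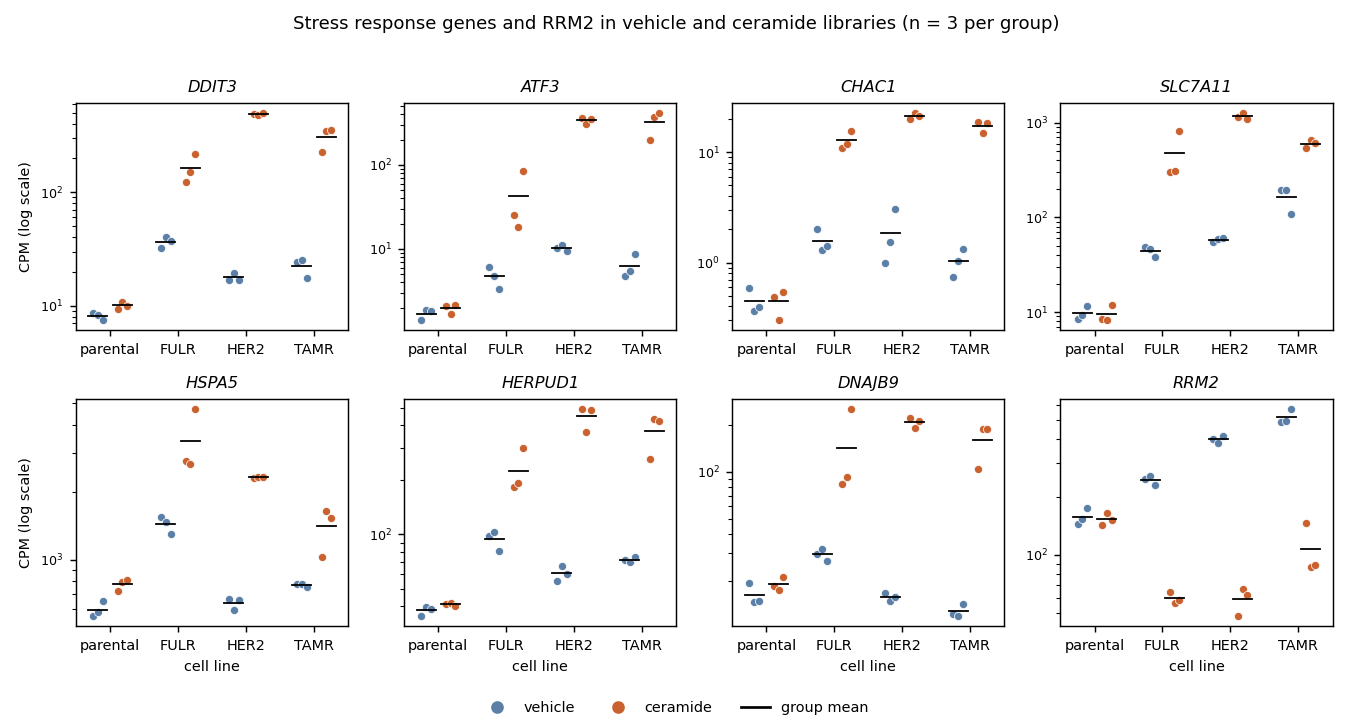
CPM of 8 genes in each of the 24 libraries on a log axis, 1 point per library and a bar at each group mean, for stress genes (DDIT3, ATF3, CHAC1, SLC7A11), ER chaperone and degradation genes (HSPA5, HERPUD1, DNAJB9) and the proliferation gene RRM2. Ceramide points of DDIT3 lie above vehicle points in FULR, HER2 and TAMR, where its log2 fold changes were 2.15, 4.77 and 3.78, against 0.31 in parental.

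Other lists gave these counts. Ribosomal protein genes rose in 6 of 27 cases in FULR (camera adjusted p = 0.0233; adjusted p = 0.606 with an estimated correlation), 14 in HER2, where 1 fell (camera adjusted p = 0.085), and 17 in TAMR (camera adjusted p = 0.00135; adjusted p = 0.595 with an estimated correlation). The FULR call ended without FULR vehicle library 2 (0.0504) or 3 (0.0869) or FULR ceramide library 1 (0.224) or 2 (0.205), and the TAMR call without TAMR ceramide library 1 (0.0504). Interferon genes rose in 2 and fell in 1 of 21 cases in FULR (camera adjusted p = 0.214), rose in 3 and fell in 11 in HER2 (0.334), and rose in 5 and fell in 2 in TAMR (0.142). IFIH1, a sensor of viral RNA, rose by 2.78 ± 0.23 in HER2 and 3.78 ± 0.25 in TAMR. Hypoxia genes rose in 5 and fell in 2 of 20 in FULR (camera adjusted p = 0.184), rose in 6 and fell in 6 in HER2 (0.646), and rose in 7 and fell in 6 in TAMR (0.846). Basal and mesenchymal genes rose in 5 and fell in 1 of 13 in FULR (camera adjusted p = 0.0849), rose in 7 and fell in 4 in HER2 (0.607), and rose in 4 and fell in 5 in TAMR (0.987). Luminal genes rose in 1 and fell in 6 of 16 in FULR (camera adjusted p = 0.214) and rose in 4 and fell in 4 in TAMR (0.949). AGR2, a secretory pathway gene of this list, rose by 2.18 ± 0.27, 3.27 ± 0.28 and 1.91 ± 0.27 in FULR, HER2 and TAMR, the first at 1.42 without FULR ceramide library 3. HER family genes rose in 1 and fell in 1 of 13 in FULR (camera adjusted p = 0.437) and rose in 5 and fell in 2 in TAMR (0.494).

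Histone genes rose in 5 and fell in 5 of 21 cases in HER2 (camera adjusted p = 0.794) and rose in 7 and fell in 1 in TAMR (0.222). LXR genes fell in 1 of 7 in HER2 (camera adjusted p = 0.794) and rose in 4 and fell in 1 in TAMR (0.257). ER stress sensors rose in 5 and fell in 4 of 12 in TAMR (camera adjusted p = 0.313), with ERN1 at 2.78 ± 0.22. NRF2 genes rose in 5 and fell in 2 of 19 in TAMR (camera adjusted p = 0.413), with HMOX1 at 3.05 ± 0.43. P53 targets rose in 11 and fell in 1 of 18 in TAMR (camera adjusted p = 0.000898; adjusted p = 0.188 with an estimated correlation). Immediate early genes rose in 5 and fell in 9 of 16 in HER2 (camera adjusted p = 0.607), with MYC at 3.21 ± 0.18 and SPRY4, a feedback inhibitor of MAPK signalling, at -4.02 ± 0.51. Drug efflux and metabolism genes rose in 5 and fell in 3 of 12 in HER2 (camera adjusted p = 0.201), with CYP1A1 at 5.77 ± 0.48. Nuclear oxidative phosphorylation genes fell in 10 and rose in 1 of 25 in TAMR (camera adjusted p = 0.012; adjusted p = 0.595 with an estimated correlation). Mitochondrially encoded genes rose in 4 and fell in 2 of 13 (0.761). The leukocyte markers ITGAM (0.60 ± 0.58) and CSF1R (0.21 ± 0.68) were not called in FULR. Fibroblast and endothelial markers rose in 0 of 5 in FULR (camera adjusted p = 0.718), rose in 1 and fell in 1 in HER2 (0.85), and rose in 1 and fell in 2 in TAMR (0.761). Adjusted over the list alone, counts of rises or falls in these 3 lines changed by at most 2 members, except for the mitochondrially encoded genes of FULR.

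**Figure D4:**
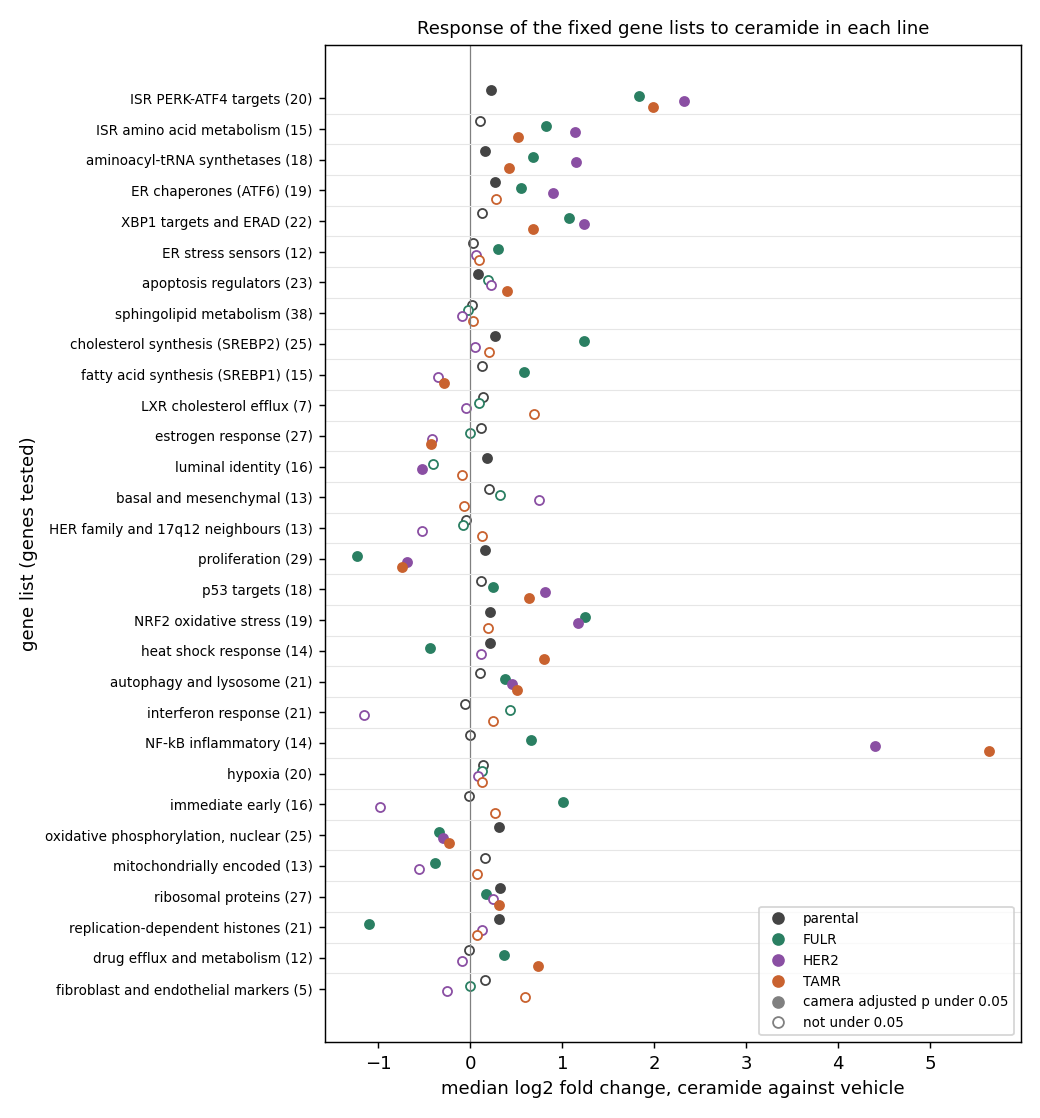
Median log2 fold change (ceramide against vehicle) of each fixed gene list in each line, 1 colour per line, with filled points where the camera adjusted p was under 0.05; numbers after list names are genes tested. PERK-ATF4 targets are at 0.23, 1.84, 2.33 and 1.98 in parental, FULR, HER2 and TAMR, and proliferation genes at 0.16, -1.23, -0.69 and -0.75.

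Calls were shared among the resistant lines, which had separate vehicle libraries. Genes higher in ceramide in FULR, HER2 and TAMR together numbered 1233 against 156.4 for independent lists, and genes lower in all 3 numbered 934 against 109.5. With a change of at least 2-fold also required these were 308 and 189, and without FULR ceramide library 3 the first was 685. DDIT3, ATF3, CHAC1, HERPUD1 and DNAJB9 rose and RRM2 fell in all 3. HER2 and TAMR shared 3123 rises against 1162.3 expected (odds ratio 18.5) and 2755 falls against 1036.7 (14.6). FULR and HER2 shared 1591 rises against 639 (7.69), and FULR and TAMR 1396 against 585.2 (5.9). Genes higher in 1 resistant line and lower in another numbered 613. No expected number was computed for them, so this count is not read as an excess. Across genes, which are not independent replicates, responses correlated at r = 0.666 between HER2 and TAMR, 0.387 between FULR and HER2 and 0.321 between FULR and TAMR, and at -0.018, 0.052 and 0.067 between parental and FULR, HER2 and TAMR.

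The interaction test asked whether a resistant line responded differently from parental cells. DDIT3 responded more in FULR (1.84 ± 0.26, adjusted p = 1.84e-05), HER2 (4.46 ± 0.27, adjusted p = 7.7e-12) and TAMR (3.47 ± 0.26, adjusted p = 3.69e-10) than in parental. ATF4 (0.55 ± 0.13, 0.96 ± 0.13 and 1.09 ± 0.13), CHAC1 (3.00 ± 0.58, 3.53 ± 0.58 and 4.06 ± 0.59), TRIB3, a CHOP target (1.19 ± 0.24, 0.93 ± 0.24 and 1.02 ± 0.24), and ERN1 (2.20 ± 0.33, 3.64 ± 0.32 and 3.06 ± 0.32) were also called in FULR, HER2 and TAMR. HSPA5 responded more in FULR (0.85 ± 0.22) and HER2 (1.48 ± 0.22) and was not called in TAMR (0.49 ± 0.22, adjusted p = 0.102), where it was called without TAMR ceramide library 1 (0.64, adjusted p = 0.0122) and with no filter (0.0296). ESR1 responded by -2.38 ± 0.22 in HER2 and -1.49 ± 0.22 in TAMR relative to parental. ERBB2 responded by -1.45 ± 0.17 in HER2, and GREB1 by 2.13 ± 0.21 and TFF1 by 2.24 ± 0.37 in HER2. In FULR, neither ESR1 (-0.59 ± 0.39) nor ERBB2 (-0.09 ± 0.17) was called.

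In all, 2502 genes responded differently in FULR (1149 with a higher log2 change than in parental, 1353 with a lower one), 6709 in HER2 (3243 and 3466) and 5342 in TAMR (2698 and 2644), and 9107 differed among the 4 lines by the F test. EGR3 had no counts in FULR vehicle and 60 in FULR ceramide, a rise of at least 20.7-fold. Its rank above NIBAN1 is therefore not settled. By fitted values EGR3 led the positive differences in FULR, followed by NIBAN1 (6.52 ± 1.09, or 5.76 without FULR ceramide library 3 and 7.45 without parental ceramide library 2). WNT11 (adjusted p = 0.0437), a Wnt ligand, led the negative ones. It had 1 count in parental vehicle and 5 in parental ceramide, against 1460 and 349 in FULR, so no size of its difference is given, and it lost its call in 7 of 12 fits without 1 library, with adjusted p up to 0.243 (without parental ceramide library 3). The others were parental vehicle libraries 1 (0.0882) and 2 (0.116), parental ceramide library 2 (0.114), FULR vehicle libraries 1 (0.0609) and 2 (0.0645) and FULR ceramide library 3 (0.0552). In HER2, NIBAN1 (8.01 ± 1.21; 8.96 without parental ceramide library 2) led the positive and MAB21L4 (-6.58 ± 0.85) the negative differences. In TAMR, by fitted values, MOV10L1, with no counts in parental ceramide, and CYP1A1 (11.37 ± 1.85) led the positive differences. IL24 and PSAT1, with no counts in TAMR ceramide, led the negative ones. PSAT1 had only 9 counts in TAMR vehicle, against 1046 and 1008 in parental vehicle and ceramide. Ranks that rest on a group with no counts are not settled. The PERK-ATF4 and proliferation lists were called in all 3, with an estimated correlation too. PERK-ATF4 targets had a higher log2 change than in parental in 17, 16 and 17 of 20 cases in FULR, HER2 and TAMR, and a lower one in 1 in HER2 (camera adjusted p = 4.25e-22, 6.08e-19 and 6.88e-22; 0.0157, 0.0221 and 0.00812 with an estimated correlation). Proliferation genes, which fell in these lines, had a lower log2 change in 27, 21 and 20 of 29 cases (camera adjusted p = 1.35e-46, 1.63e-12 and 1.02e-15; 9.68e-06, 0.0176 and 0.00378 with an estimated correlation). Adjusted over the list alone these counts moved by at most 1.

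In vehicle, the resistant lines were set against parental cells, which differed from them in medium and, for FULR and TAMR, in drug as well as in line. Estrogen target genes were lower in all 3. PGR (ENSG00000082175.14, chromosome 11, 101029624 to 101130524) was at 249 ± 19.8 CPM in parental (SD). It was at least 4000-fold lower in FULR, which had no counts, lower by 2.59 on the log2 scale in HER2 and by 5.38 in TAMR, all called. GREB1 was lower by 4.92 in FULR, 4.38 in HER2 and 8.54 in TAMR (log2). ESR1 was lower by 9.19 in FULR and 1.19 in TAMR, and higher by 0.43 ± 0.16 in HER2 (adjusted p = 0.0204), a call lost without parental vehicle library 1 (0.0771) or 2 (0.0548) or HER2 vehicle library 3 (0.0599). TFF1 was lower by 4.18 in FULR and 2.59 in HER2, and was at 0.42 ± 0.26 in TAMR (adjusted p = 0.176). There, it was called with no filter (0.00041) and without TAMR vehicle library 3 (0.70, adjusted p = 0.0139). Of 27 estrogen response genes, 23 were lower and 0 higher in FULR (camera adjusted p = 1.47e-36; adjusted p = 1.8e-07 with an estimated correlation). In HER2 20 were lower and 3 higher (3.47e-09; adjusted p = 0.000918 with an estimated correlation), and in TAMR 20 lower and 4 higher (9.73e-11; adjusted p = 0.000483 with an estimated correlation). Adjusted over the list alone, 24, 20 and 20 were lower.

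**Figure D5:**
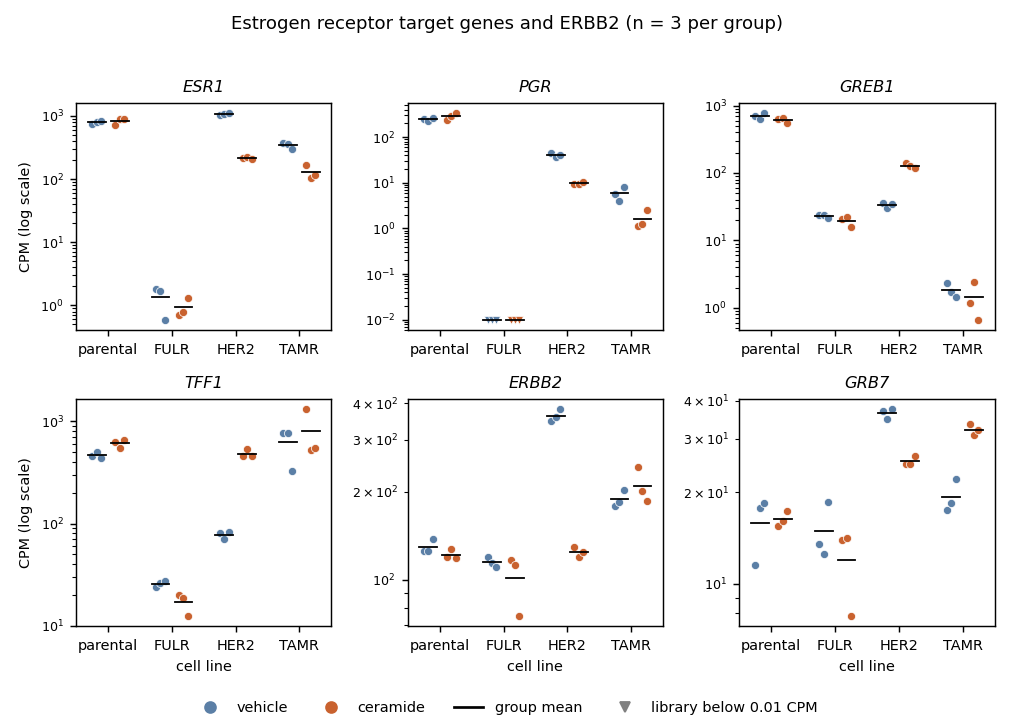
CPM of ESR1, PGR, GREB1, TFF1, ERBB2 and GRB7 in each of the 24 libraries on a log axis, 1 point per library and a bar at each group mean; triangles at 0.01 mark libraries below 0.01 CPM. ESR1 lies near 1 CPM in FULR, and ERBB2 is highest in HER2 vehicle, at 362.5 CPM.

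ERBB2 was higher by 1.48 ± 0.12 in HER2 (adjusted p = 5.81e-11) and 0.54 ± 0.12 in TAMR (adjusted p = 0.000411) than in parental, and was not called in FULR (-0.17 ± 0.12). The 17q12 neighbour GRB7 was higher by 1.19 ± 0.18 in HER2. In all, 7252 genes differed in FULR (3791 higher, 3461 lower), 10100 in HER2 (5002 and 5098) and 9859 in TAMR (4963 and 4896). In FULR, GABRB2, a GABA receptor subunit (at least 371-fold), and the keratin gene KRT4 (at least 327-fold) led the rises. PGR, the cytokine gene IL20 (at least 2580-fold) and the netrin receptor gene UNC5C (at least 954-fold) led the falls. In HER2, LDHB, a lactate dehydrogenase subunit, was 7590-fold higher (2100 to 62700, 2 parental counts) and SOX11, a neural transcription factor gene, at least 590-fold higher. The chemokine gene CXCL12 was at least 2660-fold lower and SUSD3 at least 1150-fold lower. In TAMR, LDHB was 11000-fold higher (3060 to 91200), SOX11 at least 873-fold and EYA4 at least 661-fold higher. MALRD1 was at least 6810-fold, IL20 at least 3450-fold and TENM3 at least 2050-fold lower. The drug efflux and metabolism list was called in FULR with an estimated correlation too, with 6 of 12 higher and 1 lower (camera adjusted p = 0.000661; adjusted p = 0.0156 with an estimated correlation), led by ABCG2, a multidrug transporter (7.25 ± 0.33). Fitted log2 fold changes of LDHB went from 12.63 in HER2 and 13.17 in TAMR to 15.26 and 15.79 without parental vehicle library 1 and to 11.98 and 12.51 without library 2. Interferon genes were lower in 15 and higher in 3 of 21 cases in TAMR (camera adjusted p = 0.00173; adjusted p = 0.0203 with an estimated correlation), with BST2, which tethers virions, at least 679-fold lower.

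Stress and survival genes also differed in vehicle. DDIT3 was higher by 2.17 ± 0.19 in FULR, 1.12 ± 0.19 in HER2 and 1.46 ± 0.19 in TAMR. ER chaperones were higher in 18 of 19 cases in FULR (camera adjusted p = 1.01e-10; adjusted p = 0.117 with an estimated correlation), with HSPA5 at 1.27 ± 0.16. They were higher in 8 cases in HER2 (0.181) and 13 in TAMR (0.00398; adjusted p = 0.672 with an estimated correlation). NRF2 genes were higher in 15, 13 and 17 of 19 cases in FULR, HER2 and TAMR (camera adjusted p = 4.24e-07, 0.000404 and 4.88e-07; adjusted p = 0.287, 0.897 and 0.366 with an estimated correlation), and lower in 1 in TAMR, with SLC7A11 higher by 2.18 ± 0.28, 2.56 ± 0.28 and 4.07 ± 0.30. The apoptosis inhibitor gene BCL2, an estrogen target, was lower by 8.46 in FULR, 5.97 in HER2 and 5.09 in TAMR (log2). EGFR, the epidermal growth factor receptor gene, was higher by 5.97 ± 0.28, 7.81 ± 0.28 and 7.31 ± 0.28. Basal and mesenchymal genes were higher in 7 of 13 cases in FULR, 5 in HER2 and 5 in TAMR, where 4 were lower (camera adjusted p = 0.000661, 0.00406 and 0.0252; adjusted p = 0.117, 0.211 and 0.366 with an estimated correlation). DEGS2, which makes phytoceramides, was lower by 5.12, 5.19 and 6.17, and SGMS2, a sphingomyelin synthase gene, higher by 3.16 ± 0.23, 4.77 ± 0.23 and 4.55 ± 0.23. The sphingolipid list gave no call by camera (adjusted p = 0.726, 0.566 and 0.984). Fry called it in HER2 (adjusted p = 0.00302) and not in FULR (0.389) or TAMR (0.766).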

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

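The tests of power and of medium given here, the comparisons of the resistant lines with each other and that of TAMR with HER2 in vehicle were chosen only after the results had been seen.

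The response to ceramide differed between lines by the interaction test of edgeR. Against parental, 2502 genes responded differently in FULR, 6709 in HER2 and 5342 in TAMR, and 9107 differed among the 4 lines. DDIT3, CHAC1 and ERN1 rose more than in parental in each resistant line, and RRM2 fell with ceramide in each of them. Between resistant lines, 2799 genes differed for TAMR against HER2, 5113 for FULR against HER2 and 4112 for FULR against TAMR.

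Each comparison within a line, or between lines in vehicle, has 10 splits of its 6 libraries, too few for a share under 0.05. The real split called 1 gene in parental with ceramide and the highest other split 0. In FULR the values were 4268 and 0, in HER2 9498 and 0, and in TAMR 8228 and 97. In vehicle they were 7252 and 0 for FULR against parental, 10100 and 0 for HER2, 9859 and 0 for TAMR, and 3213 and 0 for TAMR against HER2.

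For the differences in response, 100 splits were drawn, each regrouping vehicle and ceramide libraries within lines. For FULR against parental, 1 of the splits, the real one, called 2502 genes and the highest other 2351. For the 4 lines together, 3 splits called at least 9107 and the highest other called 9298. These shares are under 0.05, but a split that keeps 1 line's libraries together still carries that line's ceramide effect. The share therefore does not test a difference in response alone, and chance is not called excluded from it. The share was 0.05 or more for HER2 against parental (5 splits at 6709 or more, highest other 7322) and TAMR against parental (6 at 5342 or more, 6076). It was so too for TAMR against HER2 (14 at 2799 or more, 10665), FULR against HER2 (6 at 5113 or more, 9135) and FULR against TAMR (6 at 4112 or more, 7950). For the same reason the share decides nothing there, and chance is neither excluded nor shown by it. Counts above the real one, up to 10665 against 2799, point to a structure of the samples: every other split that called as many genes as the real one kept, or exchanged as a whole, the vehicle and ceramide libraries of at least 1 line. Among splits that mixed them in all lines (77 of 100, or 71 for the 4 lines), the highest count per comparison ran from 0 to 10.

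Ceramide gave 1 call in parental cells and 4268 to 9498 in the resistant lines. Lower power in the parental libraries as the whole cause is argued against relative to HER2 and TAMR: over 1396 genes raised in FULR and TAMR the highest median log2 change of a parental ceramide library was 0.13, against at least 1.06 in HER2, and over 1591 genes raised in FULR and HER2 it was 0.131, against at least 0.6 in TAMR. Relative to FULR, 2502 genes responded differently from parental, but the bounds of this test were set once that count was known. It replaced a test over 3123 genes raised in HER2 and TAMR, which had left lower power open. There the medians were 0.011 to 0.114 in parental and 0.229 to 0.525 in FULR libraries. Over 2755 genes lowered in HER2 and TAMR they were -0.026 to 0.024 in parental and -0.44 to -0.186 in FULR. These ranges did not overlap, and recovery of simulated 2-fold and 4-fold changes was 62% and 79% in parental and 61% and 87% in FULR. The values argue against lower power as the whole cause relative to FULR too, while a part played by it stays open. A partial exchange of labels between treated and untreated parental libraries, hiding a large response, is argued against, since the most genes any other split of the 6 called was 0. A full exchange is the same split with its direction reversed. It would leave the number of calls as it is, so the other splits cannot test it. The medium of the parental line cannot be told apart from the line, since 0 resistant lines grew in it, and a difference in biology between the lines, or in the nuclear share of the RNA, stays open and untested.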

How the results depend on the processing

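All settings of the comparisons between resistant lines, the fits without both libraries that stood apart (FULR ceramide library 3 and TAMR ceramide library 1), the overlaps without single libraries and the parental count without libraries of other lines were chosen only after the results had been seen.

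Of 5772 values of 417 pairs of a named gene and a comparison under the other settings, 5700 kept their direction and side of the threshold, 24 newly passed it, 43 no longer passed and 5 changed direction, over 27 pairs. The 5 were of genes not called in TAMR with ceramide. ERBB2 went from 0.15 to -0.006 without TAMR ceramide library 1 and -0.005 without both libraries that stood apart, with a range of -0.006 to 0.196 over single libraries left out. TFF1 went from 0.35 to -0.001 without TAMR vehicle library 3, -0.257 without TAMR ceramide library 1 and -0.256 without both, with a range of -0.257 to 0.537. Of 1689 camera or fry values of the 129 lists called by camera, 1523 stayed called and 166 did not. Of the 166, 106 were with the estimated correlation, 13 with fry, 43 without single libraries and 4 without both. RLE scaling ended 0 list calls and moved the median of all genes by at most 0.023. For each change of this paragraph the cause was not tested.

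The 1 call for ceramide in parental became 133 with no low-count filter, 272 with DESeq2, 17 with only the parental libraries, 0 to 80 without single libraries and 524 without both. The 4268 calls in FULR became 2444 with only the FULR libraries and 2781 (without FULR ceramide library 3) to 4324 without single ones. TAMR against HER2 in vehicle gave 5424 in place of 3213, and FULR against TAMR in response 2703 in place of 4112, with only the groups compared; the cause was not tested. Without single libraries HER2 gave 8497 to 8736 calls and TAMR 7011 to 8652, and the differences in response from parental 1898 to 2852 in FULR, 6070 to 6371 in HER2 and 4556 to 6327 in TAMR. Totals of calls of the other comparisons stayed within 1.5 times under the settings run. Of rises and falls taken apart, the 2391 rises in FULR became 1531 without FULR vehicle library 2, 1252 without FULR ceramide library 3, 1094 with only the FULR libraries and 1575 without both libraries that stood apart. For TAMR against HER2 in vehicle, the 1526 rises became 1005, 943 and 944 without HER2 vehicle library 1, 2 or 3, and 2695 with only the groups compared. Its 1687 falls became 2729 with only those groups and 2597 without both libraries. In response, the 1249 falls of TAMR against HER2 became 1989 without both. The 2087 falls of FULR against TAMR in response became 1314 with only the groups compared. For these the cause was not tested.

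Lists called by camera for ceramide fell with the estimated correlation from 12 to 0 in parental, 20 to 3 in FULR, 12 to 3 in HER2 and 15 to 4 in TAMR, and with fry were 3 in parental and 23 in HER2. For the difference from parental they fell from 18 to 3 in FULR, 13 to 2 in HER2 (20 with fry) and 14 to 3 in TAMR. In vehicle they fell from 14 to 2 in FULR, 4 to 1 in HER2 (20 with fry) and 7 to 2 in TAMR (17 with fry). For these the cause was not tested. Genes raised in FULR, HER2 and TAMR together went from 1233 to 308, and lowered from 934 to 189, when at least a 2-fold change was required, as a stricter rule must lower them. The odds ratios of genes raised went with this rule from 7.69 to 12.2 for FULR and HER2, 5.9 to 9.81 for FULR and TAMR and 18.5 to 29.6 for HER2 and TAMR. Those raised were 685 (without FULR ceramide library 3) to 1225 without single libraries, and the cause was not tested.

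With the replicate number as a replicate block, the parental count was 0, since RPS3P7 had an adjusted p of 0.0691, and all other counts stayed within 1.5 times (4263, 9437 and 8172 calls for ceramide in FULR, HER2 and TAMR). The numbers did not pair the samples: deviations of same-numbered libraries correlated at a median of -0.004 (-0.106 to 0.09), against -0.006 for other pairs, and 3 of 12 matched their own number best. Depth limits low genes, since 3 counts over a group are 0.0442 to 0.0737 CPM.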

Other observations

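The comparisons of resistant lines with each other, the test of scaling and the tests of genes on in some lines and off in others, were chosen only after the results had been seen.

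Responses of some gene lists to ceramide differed between TAMR and HER2 cells. The log2 change of heat shock genes was higher in TAMR than in HER2 in 12 of 14 cases (camera adjusted p = 3.43e-17; adjusted p = 0.0267 with an estimated correlation) and lower in FULR than in TAMR in 11 of 14 (5.48e-29; adjusted p = 0.00315 with an estimated correlation). That of luminal identity genes, 9 of which fell in HER2 and 4 in TAMR, was higher in TAMR in 9 and lower in 3 of 16 cases (1.4e-05; adjusted p = 0.0267 with an estimated correlation), and that of interferon genes higher in 5 of 21 (0.00443; adjusted p = 0.0425 with an estimated correlation). NF-kB genes had a lower log2 change in FULR than in TAMR in 8 of 14 cases (1.59e-12; adjusted p = 0.00367 with an estimated correlation). By contrast 12 of 18 aminoacyl-tRNA synthetases had a lower log2 change in TAMR than in HER2 (9.19e-12; adjusted p = 0.0947 with an estimated correlation). CYP1A1 had the largest positive difference of TAMR from HER2 (5.66 ± 1.10), then ID1 (4.97 ± 0.77; 2.63 without TAMR ceramide library 1). ERBB2 (1.70 ± 0.17) and ESR1 (0.90 ± 0.22) also had positive differences, since ERBB2 fell in HER2 only and ESR1 fell less in TAMR, while SLC7A11 (-2.47 ± 0.36), GREB1 (-2.36 ± 0.32; -2.96 without TAMR ceramide library 2) and TFF1 (-2.28 ± 0.37; -2.89 without TAMR ceramide library 1), which rose in HER2, had negative ones. BTN3A3 had the lowest difference of the genes called (-2.76 ± 0.94, adjusted p = 0.0454), but was not called without any 1 of 8 libraries, and was at -3.98 without HER2 vehicle library 1.

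In vehicle, the 4 members of the immediate early list with the largest changes were higher in HER2 and TAMR than in parental. SPRY4 was at 0.62 CPM in parental and 340.1 and 486.4 CPM in HER2 and TAMR, log2 fold changes of 9.09 ± 0.74 and 9.61 ± 0.74. The phosphatase gene DUSP6 was higher by 5.60 ± 0.57 and 5.42 ± 0.57, ETV4 by 5.86 ± 0.29 and 6.45 ± 0.29, and ETV5 by 7.23 ± 0.52 and 7.47 ± 0.52 (9.79 and 10.03 without parental vehicle library 2). Immediate early genes as a list were higher in 13 and lower in 2 of 16 cases in HER2 (camera adjusted p = 3.27e-05; adjusted p = 0.211 with an estimated correlation) and higher in 11 and lower in 3 in TAMR (0.000935; adjusted p = 0.366 with an estimated correlation).

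Ribosomal protein genes and nuclear oxidative phosphorylation genes had median log2 changes of 0.328 and 0.309 with ceramide in parental. Both medians lay at percentile 100 of 10000 random lists matched on exonic length (upper bounds of the central 95%, 0.178 and 0.169). Lists matched on expression too had medians of 0.211 and 0.183 (upper bounds 0.271 and 0.243), so much of the shift was shared by genes of like length and level. Exonic length here was the union of all annotated exons, which can exceed the length of the transcripts in the cells. Members of random lists were also drawn independently, while those of the ribosomal and oxidative phosphorylation lists correlated at 0.65 and 0.46. Whether transcript length was the whole cause therefore cannot be decided by this test. A library factor shifts all genes alike, so scaling by itself cannot set ribosomal proteins above lists matched on length and expression. Their median lay at percentile 100 of those lists. This value was already known when the test of scaling was set, so it is no separate evidence on scaling. The medians of the 3 ceramide libraries were 0.483, 0.145 and 0.365 for ribosomal proteins, against 0.05, 0.077 and -0.123 in vehicle, and the first of them also stood apart in the correlation of its deviations with length (-0.236, against -0.029 to 0.101 in the other 5 parental libraries). A response to ceramide in parental cells may be among the open explanations, but with an estimated correlation neither list was called (adjusted p = 0.322), so a shift shared by a few libraries stays open too.

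Some genes were on in HER2 and TAMR (at least 10 CPM in vehicle) and off in parental and FULR (at most 3 counts), or the converse: LDHB, ROBO2 and CXCL8 were among 10 of the first kind and TENM3, FABP5 and SIGMAR1 among 17 of the second. The growth medium without estrogen was shared by FULR, HER2 and TAMR, so it alone cannot part parental and FULR from HER2 and TAMR. Only 2 genes, MEIS2 and GATA4, parted parental from the other 3 lines, against 27, but this count is no separate test of the medium. With 1 line behind both labels, HER2 and TAMR might share these states; 3213 genes differed between them in vehicle, but their media differ in 4-hydroxytamoxifen, so this cannot be told apart from separate lines. A common history or a shared change on the way to resistance stays open as a hypothesis, untested here.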
